A study of Homo sapiens with 8 samples.

How the data were processed

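FAIRE-seq libraries were made from formaldehyde-fixed AIRE-Tet cells, with 10% of each sample set aside as input, per the labels' protocols. The labels give 4 groups of 2 independent biological replicates, TruSeq ChIP library preparation and paired-end reads of 100 bp from a HiSeq 2000, with each library sequenced 2 times. Trim Galore, Bowtie2 and Bowtie and the hg19 build are named in the submitters' processing notes, without versions. How each aligner was used, how fragments were counted, how windows were chosen, how duplicate reads were treated and whether input was subtracted are not given in the sources used here. Input libraries were not analysed here.

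The deposited table gives raw counts per window, 1 column per library, in windows of 150 bp that start every 50 bp. Each of the 256141 windows held at least 111 counts over the 8 libraries, with a median of 160 and a maximum of 5688, so the authors' table holds only windows that passed some minimum. The column totals, from 4489871 to 8275911, are sums over overlapping windows and not library depths. They were 4489871 to 5305079 in the AIRE-induced libraries and 4568818 to 8275911 in the others. The last window on chromosome 1 ends at 249153350, beyond the last gene of the GRCh38.p14 table at hand (248937099), so that table's coordinates were not used and no genes were assigned. The lists of genes and the promoter and gene-body classes fixed beforehand could therefore not be tested, and the genes fixed by name have no values here.

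Windows were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests (glmQLFit and glmQLFTest, two-sided) after TMM scaling on the column totals, with Benjamini-Hochberg adjustment at 0.05. filterByExpr removed 0 windows. A model with 1 mean per group over all 8 libraries (4 residual degrees of freedom) gave Dox vs Control, Etop vs Control, DoxEtop vs Control, DoxEtop vs Dox, DoxEtop vs Etop and the interaction. An additive model of AIRE induction and etoposide (5 residual degrees of freedom) gave both main effects. The common biological coefficient of variation was 26.4%. Overlapping windows share fragments, so counts of windows are not counts of independent events. For this reason windows with gaps of 100 bp or less were merged and Simes' p per region was adjusted over the 35741 regions. Levels are CPM (counts scaled to the TMM-adjusted column total), and log2 CPM used a prior count of 2. For 4 libraries against 4, exact permutation tests over all 70 assignments were two-sided, with a smallest p of 0.0286. For 2 against 2 the smallest exact p is 0.333, so no such test was made. Fold changes against libraries that all had 0 counts are lower bounds computed with 3 counts per library. Where a group held 1 to 3 counts, the ratio of pooled levels has an exact 95% interval from the binomial distribution (Clopper-Pearson), which covers counting error only.

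The named windows follow a rule fixed before the data were examined. In a comparison with 20 or more calls, they are the 10 windows with the highest and the 10 with the lowest log2 fold change among called windows whose mean level was above the median and whose groups did not overlap. In other comparisons they are all called windows and, as values only, the 5 windows with the smallest p. The classes by region width, chromosome and 1 Mb segment were chosen after seeing the data.

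The authors' minimum on counts can favor windows high in the libraries without induction, whose totals summed to 26766111 against 19999382 in the induced libraries. After seeing the data, 4 selections of windows were therefore tried, with the calls of the whole table kept. The first left out the 274 windows that would fall below 111 counts with the arms exchanged. The minimum was not sharp, with 2 windows at 111 counts and 3944 at 129, the most frequent sum, so the second required 129 counts both before and after the exchange and kept 203907 windows. The third kept the 85936 windows with a mean of both arms of at least 3.96 CPM, at which the summed count would reach the median of 160 even if all counts came from the induced arm. The fourth kept as many windows by summed count, to set coverage apart from like treatment of the arms. In simulated changes made equally often down and up, 54.29% of windows with at least 111 counts were lower, against 50.05%, 50.09% and 50.18% with the first 3 selections. The simulated changes were all of the same large size, with counting noise only and no test for calls. These shares therefore check that the selections treat the arms alike and do not estimate the tilt among called windows.

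Replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 1.85 to 3.12 over 1 window per region, so no library was counted as a repeat of another. The procedure was tested on simulated counts drawn from the means and totals of these libraries, with 100 windows changed 2-fold and 100 changed 4-fold among 256141. For Dox vs Control it called 1 of the 100 windows changed 2-fold and 32 of those changed 4-fold, with 3 false calls. For the AIRE main effect it called 12 and 78, with 7 false calls, and 0 windows had the wrong sign.

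Alternatives fixed before the data were examined were DESeq2's size factors, scaling by column totals alone, loess offsets from limma 3.58.1 (fitted to log2 of counts plus 0.5), no filter, a stricter filter on mean level at the 25th percentile (192106 windows), DESeq2 1.42.0, limma-voom, the replicate number as a block, the 4 libraries of a comparison alone, and leaving out each library in turn. Testing 1 window per region, thinning all libraries to equal totals, and merging with gaps of 0 or 500 bp were added after seeing the data.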

Results

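Open chromatin was profiled by FAIRE-seq in AIRE-Tet cells, a line derived from human embryonic kidney HEK293 cells in which doxycycline switches on expression of human AIRE. AIRE, the autoimmune regulator, is a transcription regulator that acts in the thymus, where it drives the expression of many tissue-restricted genes. FAIRE-seq sequences the DNA that stays in the aqueous phase after formaldehyde fixation and phenol-chloroform extraction, which is enriched for DNA poorly bound by nucleosomes. Etoposide is a drug that traps topoisomerase II on DNA and leaves DNA breaks. The design crossed both treatments into 4 groups of 2 biological replicates: untreated cells (Control), cells given 1.5 µM doxycycline (Dox), cells given 2 µM etoposide for 24 h (Etop), and cells given etoposide after 24 h of AIRE induction (DoxEtop). The comparisons ask whether AIRE induction, etoposide or both together go with a change in chromatin openness. Doxycycline without the AIRE transgene was not analysed here, so "AIRE induction" below stands for doxycycline treatment of these cells, and the drug and AIRE itself cannot be separated.

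The deposited table held raw counts in 256141 overlapping windows of 150 bp, placed every 50 bp on the hg19 build. Windows separated by gaps of 100 bp or less were merged into 35741 regions with a median width of 350 bp. Total window counts were 8275911 and 6787276 in Control, 5169600 and 4489871 in Dox, 7134106 and 4568818 in Etop, and 5305079 and 5034832 in DoxEtop. A fragment can fall in several windows and reads outside the windows are not in the table, so these totals are not library depths and a change of the same size at every window would not be seen. The windows carried no gene names and no gene annotation of the hg19 build was used here, so regions are named by chromosome, start and end.

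AIRE induction was the main difference between the libraries. The first principal component of log2 CPM (the count scaled to the library total) held 38.4% of the variance, and the 4 AIRE-induced libraries scored 104.9 to 227.2 on it, against -240.9 to -40.6 for the 4 libraries without induction. No other division of the 8 libraries into 4 and 4 parted them by as much (exact permutation test, two-sided, p = 0.0286, the smallest this design can give), whereas etoposide did not order the scores (exact p = 0.943). Correlations of log2 CPM across windows, which are not independent replicates, were 0.350 to 0.547 between replicates of a group, with a median of 0.480 between groups of the same AIRE state and 0.188 between libraries of different AIRE state. Among libraries without induction, Control replicate 1 scored closest to the induced libraries. It correlated with Dox replicate 1 at 0.507, above its 0.488 with Control replicate 2, and with all 4 induced libraries at 0.369 to 0.507, against 0.357 with Etop replicate 1 and 0.461 with Etop replicate 2. Control replicate 2 and Dox replicate 1 had 0.189.

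**Figure D1:**
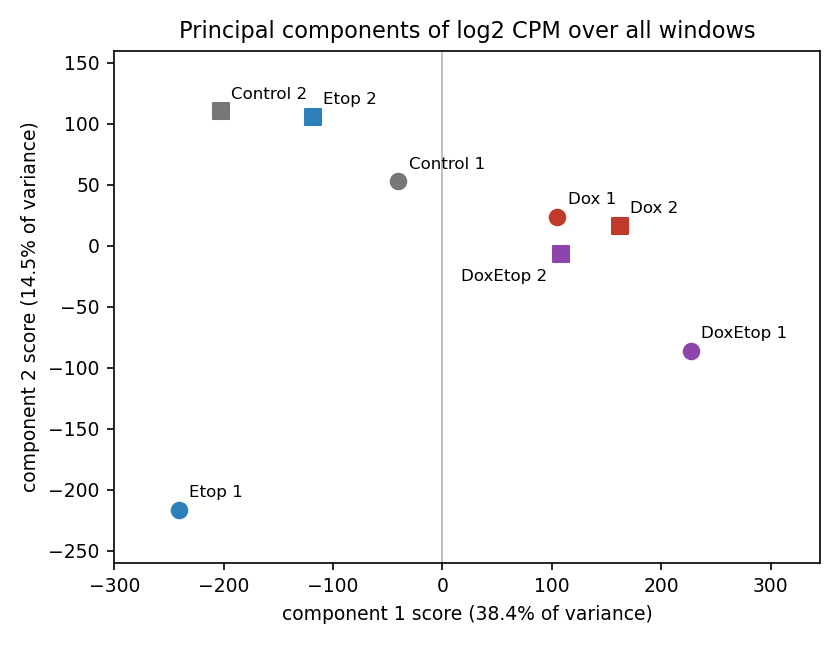
Scores of the 8 libraries on the first 2 principal components of log2 CPM over all windows, with color for group, circles for replicate 1 and squares for replicate 2. All AIRE-induced libraries lie above 100 on component 1 and all others lie below 0, with Control replicate 1 nearest to the boundary at -40.6.

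Over all 8 libraries, AIRE induction went with a loss of FAIRE signal at many more windows than it went with a gain. With etoposide held as a second factor, 15809 windows were lower and 3253 were higher in the 4 AIRE-induced libraries than in the 4 others, so that 82.9% of the 19062 called windows were lower. The median log2 fold change was -1.49 for the windows called lower and 1.17 for those called higher. Tested as merged regions, 4599 regions had their strongest window lower and 509 had it higher. The test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, as for all window counts given here unless another tool is named.

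The deepest losses left almost no reads in the induced libraries. In the region on chromosome 17 from 1619351 to 1620700, the window starting at 1620451 had 0 to 1 counts in each AIRE-induced library and 14 to 111 in each other library, a mean of 0.103 ± 0.119 CPM against 7.55 ± 6.41 CPM (SD, n = 4 each). Its pooled level was 77.3-fold lower with induction (95% counting interval 21.1 to 643), with a log2 fold change of -5.97 (SE 0.676) and an edgeR adjusted p of 2.39e-08. On chromosome 1, the window starting at 210001151, in the region from 210001101 to 210001700, had 0 to 4 counts against 36 to 76, with a log2 fold change of -4.65 (SE 0.505) and an edgeR adjusted p of 8.3e-09. On chromosome 19, windows in the regions from 36546701 to 36547450, from 35738451 to 35741700 and from 44617201 to 44617950 had log2 fold changes of -5.26, -4.61 and -4.47, with at most 3 counts in any induced library. The libraries without induction had 6 to 75, 24 to 62 and 18 to 72 counts there, and Control replicate 1 had the 6. A window starting at 226735551 on chromosome 1 (region 226735451 to 226735750) had a log2 fold change of -4.79, and a window starting at 23564451 on chromosome 14 (region 23563701 to 23564850) had -4.46. The 10 lowest named windows lay in 7 regions on 4 chromosomes. The intervals and the lower bounds given here cover counting error only.

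Gains with AIRE induction were smaller. The 10 highest named windows lay in 10 regions, with log2 fold changes of 1.55 to 1.81. The window starting at 74349751 on chromosome 17 (region 74349051 to 74350500) rose from 1.89 ± 1.39 to 6.17 ± 1.64 CPM (SD, n = 4 each), a log2 fold change of 1.81 (SE 0.374) with an edgeR adjusted p of 0.000737. On chromosome 2, the window starting at 232575051 (region 232574851 to 232575350) rose from 2.27 ± 0.491 to 7.12 ± 1.97 CPM, a log2 fold change of 1.64 (SE 0.317) with an edgeR adjusted p of 0.000298. Windows in the regions on chromosome 19 from 41195351 to 41198450 and on chromosome 10 from 73078501 to 73079750 had log2 fold changes of 1.77 and 1.67.

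The count of 19062 fell to 859 windows with limma-voom, to 7357 without Control replicate 2, to 8991 without DoxEtop replicate 1 and to 11637 without Dox replicate 2, with more lower than higher windows each time. With intensity-dependent loess offsets 15111 windows were called, 11158 of them lower, but none of the 10 lowest named windows was (edgeR adjusted p = 0.101 to 0.923), with log2 fold changes of -1.56 to 0.35 and above 0 at 36547201 on chromosome 19 and 226735551 on chromosome 1, while all 10 highest stayed called. These offsets are fitted to the same counts along each window's mean log count. With at least 111 summed counts per window, that mean is lowest where some libraries are near 0. The offsets can therefore take out a loss at such windows, so they do not decide whether these losses are real.

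**Figure D2:**
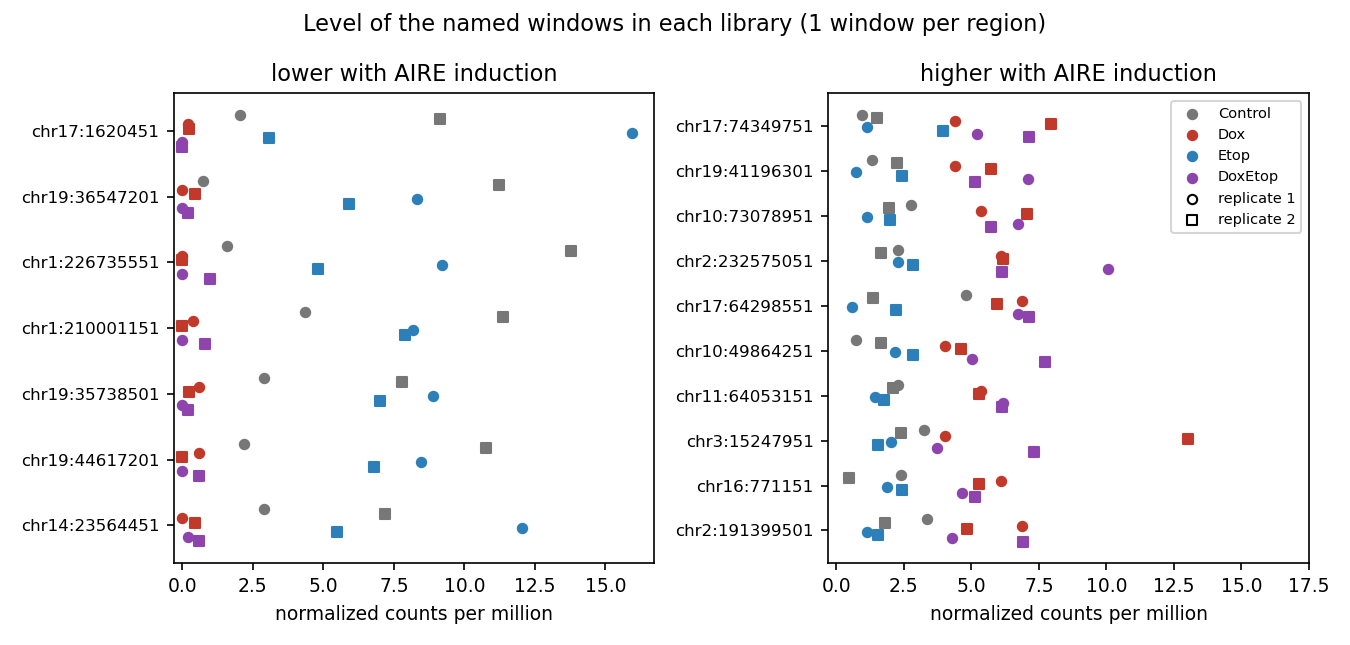
Normalized level in CPM (horizontal axes, separate scales) of the named windows of the AIRE main effect, 1 window per region, with each point a library, color for group, circles for replicate 1 and squares for replicate 2. In the left panel the induced libraries (Dox, DoxEtop) lie near 0 at windows called lower, and in the right panel they lie above all libraries without induction at windows called higher.

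In the table as deposited, the change with AIRE induction differed between narrow and wide regions. In regions of up to 300 bp, the median level per library, as log2 relative to the mean of all 8 libraries, was -0.0768 ± 0.061 in the induced libraries and 0.158 ± 0.083 in the others (SD, n = 4 each), a difference of -0.235. In regions of over 300 and up to 500 bp the difference was -0.0839. In regions of over 1000 and up to 2000 bp it had the opposite sign, at 0.098. Each of these differences separated the arms completely (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.0477 over the 5 width classes), and regions of over 500 and up to 1000 bp (0.0528, exact p = 0.0571) and over 2000 bp (0.0381, exact p = 0.114) did not pass. In regions of up to 300 bp, 9.93% of windows were called lower and 0.533% higher, against 4.64% and 1.73% in regions of over 1000 and up to 2000 bp. DoxEtop replicate 1 stood apart in the narrowest class, at -0.167. Region width is set by which windows the table holds, so the classes were formed again from windows selected alike in both arms. With 203907 windows that had at least 129 counts both as they were and with the arms exchanged, the difference was -0.157 in regions of up to 300 bp and 0.106 in those of over 1000 and up to 2000 bp (exact permutation test, p = 0.0286, adjusted p = 0.0358 each). With the 85936 windows at a mean of both arms of at least 3.96 CPM, it was 0.00533 in regions of up to 300 bp (exact p = 0.771), and no width class passed (adjusted p = 0.214 to 0.771). With these 85936 windows classed by their region width in the whole table, it was -0.269 in the 394 windows of regions of up to 300 bp, 0.126 in those of over 1000 and up to 2000 bp and 0.105 in those of over 2000 bp (exact p = 0.0286, adjusted p = 0.0477 each). The loss in regions of up to 300 bp thus held in regions formed again at 129 counts. It was not seen in regions formed by the windows of higher level alone. Regions of over 1000 and up to 2000 bp formed by those windows were at 0.0888 (exact permutation test, p = 0.0571), so a contrast there is not excluded. At 129 counts, regions of over 300 and up to 500 bp were at -0.0175 (exact permutation test, p = 0.371). Widths from the whole table are still set by which windows it holds, so that classing cannot settle this.

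**Figure D3:**
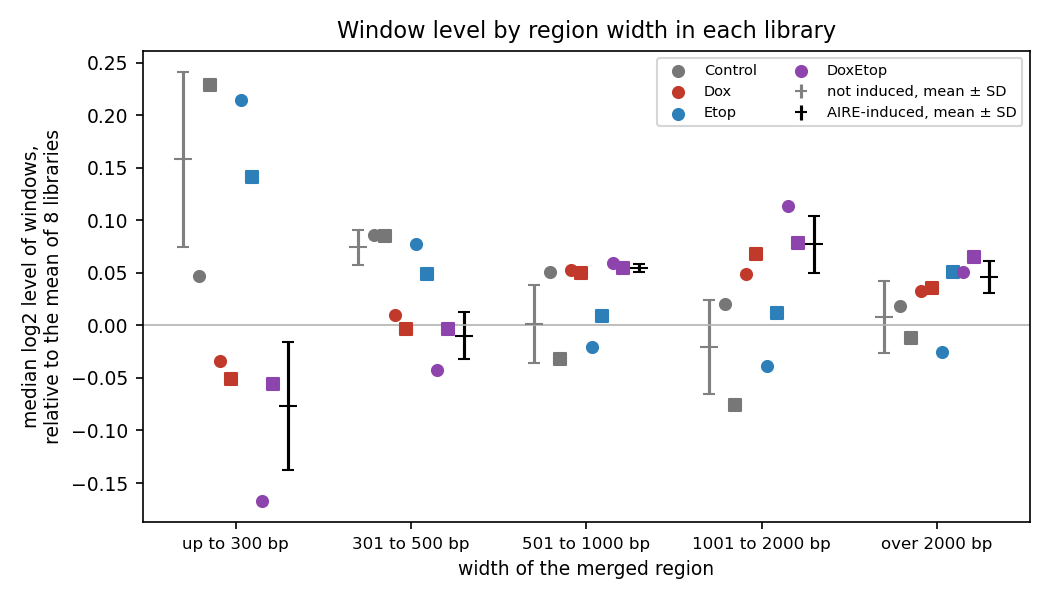
Median log2 level of windows in each library, relative to the mean of the 8 libraries, by width of the merged region, with circles for replicate 1, squares for replicate 2 and bars for the mean ± SD of the 4 libraries of each arm. Induced libraries lie below the others in regions of up to 500 bp and above them in regions of over 1000 and up to 2000 bp.

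Chromosome 19 held 15% of all windows but 24.4% of the windows called lower with AIRE induction and 13.4% of those called higher. Of its 38412 windows, 3854 were lower and 437 were higher. The induced libraries differed from the others by -0.138 in its median log2 level (exact permutation test, two-sided, p = 0.0286). Over the 23 chromosomes tested, 6 reached that smallest p and 0 passed Benjamini-Hochberg adjustment (exact test, adjusted p = 0.11 for chromosome 19). With that smallest p, a single chromosome could not pass adjustment over 23, however large its change.

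AIRE induction in cells without etoposide (Dox vs Control) lowered FAIRE signal at 2172 windows and raised it at 40, in 656 and 6 merged regions. The window starting at 226735551 on chromosome 1 had 0 counts in both Dox libraries against 13 and 92 in Control, at least 11.4-fold lower with a floor of 3 counts per library (edgeR adjusted p = 0.000647, n = 2 each). On the same chromosome, the window starting at 210001151 had 0 and 2 counts in Dox against 36 and 76 in Control, 36.6-fold lower (95% counting interval 9.89 to 306), with an edgeR adjusted p of 0.000458. Windows in the regions on chromosome 14 from 77506651 to 77507150 and on chromosome 10 from 79685251 to 79687050 had 0 to 2 counts in either Dox library against 25 to 77 in Control. Among the windows called higher, that at 74349751 on chromosome 17 had 6.16 ± 2.51 CPM in Dox and 1.23 ± 0.378 in Control (SD, n = 2 each), a log2 fold change of 2.32 (SE 0.544) with an edgeR adjusted p of 0.0207. The count was not stable when single libraries were left out. Where the library left out belonged to this comparison, 1 library stayed in its group. A drop in the count then cannot be told apart from lost replication. With all libraries, the count was 258 with DESeq2, 5 with limma-voom and 918 with loess offsets, with more lower than higher windows under each. Of the 20 named windows, DESeq2 called 0 and loess offsets 3. The log2 fold change at 210001151 on chromosome 1 was -5.115 by edgeR, -5.3 with DESeq2 and -2.233 with loess offsets. At 226735551 it was -8.463, -7.684 and -7.819 in the same order. With 0 counts in both Dox libraries there, these values do not measure the size of the loss.

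AIRE induction in cells with etoposide (DoxEtop vs Etop) lowered signal at 6226 windows and raised it at 1153, in 1917 and 219 merged regions. The window starting at 1620451 on chromosome 17 had 0 counts in both DoxEtop libraries against 14 and 111 in Etop, at least 18.8-fold lower with a floor of 3 counts per library (edgeR adjusted p = 4.41e-05, n = 2 each). A neighboring region on that chromosome, from 1617101 to 1618900, had a window with 0 and 2 counts in DoxEtop against 29 to 105 in Etop, 60.5-fold lower (95% counting interval 16.4 to 505). Windows in the regions from 35738451 to 35741700, 36546701 to 36547450 and 44405701 to 44406450 on chromosome 19 had 0 to 1 counts in either DoxEtop library against 27 to 62 in Etop. The highest was a window starting at 25574351 on chromosome 1 (region 25572951 to 25574550), with 7.02 ± 4.33 CPM in DoxEtop and 0.582 ± 0.417 in Etop, a log2 fold change of 3.68 (SE 0.648) with an edgeR adjusted p of 0.000688. Higher windows made up 15.6% of the calls, and 31.3% of 4917 calls with loess offsets. With loess offsets the window at 1620451 on chromosome 17 was no longer called (adjusted p = 0.338). Its log2 fold change was -8.84 (SE 1.22) with TMM scaling and -7.68 (SE 4.12) with loess offsets. A fold change against 0 counts has only a lower bound, so neither value measures the size of the loss. In the AIRE main effect, where each Dox library had 1 count at this window, it was -0.73 with loess offsets. In DoxEtop vs Etop, the windows at 35738501 and 36547251 on chromosome 19 were not called with loess offsets either. Their log2 fold changes went from -6.09 to -2.61 and from -5.97 to -1.20. DESeq2 did not call the window at 36547251 (adjusted p = 0.158), although its log2 fold change there was -6.245. The count was 80 without DoxEtop replicate 1, 1266 without Etop replicate 1 and 15686 without Etop replicate 2, and it was 2255 with DESeq2 and 27 with limma-voom, which split into 14 lower and 13 higher.

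The changes with AIRE induction in cells without and with etoposide, which share no library, resembled each other. Log2 fold changes of Dox vs Control and DoxEtop vs Etop correlated at Pearson r = 0.547 and Spearman rho = 0.483 across windows, which are not independent replicates, and 67.3% of windows had the same sign. Of the windows called lower, 1252 were shared, where independent lists of those sizes would share 52.8. At 1 window per region, 212 were shared against 11.6. Both lists come from 1 fit with shared estimates of spread, so the numbers for independent lists are not strict chance values. Of the windows lower in DoxEtop vs Etop, 97.3% had a log2 fold change below 0 in Dox vs Control, and 0 windows were called in opposite directions. The 40 and 1153 windows called higher shared 0, with 0.18 for independent lists, although 81.6% of the 1153 had a log2 fold change above 0 in Dox vs Control.

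Cells given both treatments differed from untreated cells (DoxEtop vs Control) at 4197 windows, 3803 lower and 394 higher, in 1130 and 60 merged regions. The window starting at 1620451 on chromosome 17 had 0 counts in both DoxEtop libraries against 17 and 61 in Control, at least 9.04-fold lower (edgeR adjusted p = 0.00064, n = 2 each). On chromosome 19, the window starting at 44405951 had 1 count in each DoxEtop library against 41 and 91 in Control, 45.9-fold lower (95% counting interval 12.5 to 383), with an edgeR adjusted p of 3.05e-05. The highest was the window starting at 108731801 on chromosome 6 (region 108731801 to 108732100), with 6.55 ± 1.09 CPM in DoxEtop and 1.04 ± 0.407 in Control (SD, n = 2 each), a log2 fold change of 2.61 (SE 0.583) with an edgeR adjusted p of 0.011. A window starting at 170604851 on the same chromosome (region 170604601 to 170605400) had 7.32 ± 1.12 CPM in DoxEtop and 1.23 ± 0.378 in Control. The count was 0 without DoxEtop replicate 1, 11 without Control replicate 2, and 6695 and 6786 without Etop replicate 1 and 2, libraries outside this comparison. It was 850 with DESeq2, 41 with limma-voom, of which 22 were lower, and 2489 with loess offsets. The window at 1620451 on chromosome 17 was not called with loess offsets (adjusted p = 0.397), and that at 108731801 on chromosome 6 was not called with DESeq2 (adjusted p = 0.235). At 108731801 the log2 fold change stayed about as large with DESeq2, from 2.61 to 2.65. At 1620451 it was -8.01 with TMM scaling and -7.61 with loess offsets. With 0 counts in both DoxEtop libraries, neither of these 2 values measures the size of the loss.

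Etoposide went with no window past the threshold in cells without AIRE (Etop vs Control) by edgeR, with 14273 windows (5.57%) at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The smallest unadjusted p was at the window starting at 66803201 on chromosome 2 (region 66803001 to 66803350), with 1 count in each Etop library against 29 and 30 in Control, 22.7-fold lower (95% counting interval 6.01 to 192) but with an edgeR adjusted p of 0.387. A window in the region on chromosome X from 133118901 to 133120200 also had 1 count in each Etop library, against 27 and 28 in Control (edgeR adjusted p = 0.771). The count was 218 without Etop replicate 2 and 13 without Control replicate 2.

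In AIRE-induced cells (DoxEtop vs Dox), edgeR also called 0 windows for etoposide, with 10923 (4.26%) at an unadjusted p under 0.05, while DESeq2 called 0 and limma-voom 8, all higher. The smallest unadjusted p was at the window starting at 1734001 on chromosome 7 (region 1733851 to 1734200), with 7.40 ± 0.17 CPM in DoxEtop and 1.31 ± 0.299 in Dox (SD, n = 2 each; edgeR adjusted p = 1). Fitted to the 4 libraries of both groups alone, 13 windows were called, all higher.

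Over all 8 libraries the etoposide main effect was 0 windows by edgeR, with 14937 (5.83%) at an unadjusted p under 0.05, 3 windows by DESeq2 and 0 by limma-voom, and edgeR called 23 without Etop replicate 1 and 6 without Control replicate 2. The window with the smallest p, starting at 235026751 on chromosome 1 (region 235026751 to 235026950), had 0.780 ± 0.459 CPM with etoposide and 4.47 ± 0.586 without it (SD, n = 4 each), a log2 fold change of -2.51 (SE 0.457) with an edgeR adjusted p of 0.198. On chromosome 6, the window starting at 31744951 (region 31744301 to 31745400) had 9.59 ± 2.19 CPM with etoposide and 3.75 ± 0.671 without it (edgeR adjusted p = 0.249). The log2 fold changes of Etop vs Control and DoxEtop vs Dox, which share no library, correlated at Pearson r = 0.075 and Spearman rho = 0.0755 across windows, and 52.5% of windows had the same sign. In data simulated from these libraries, 71 of 100 windows given a 4-fold etoposide main effect were called and 6 of 100 given a 2-fold one, so 2-fold changes at single windows were rarely detected at this depth and replication.

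**Figure D4:**
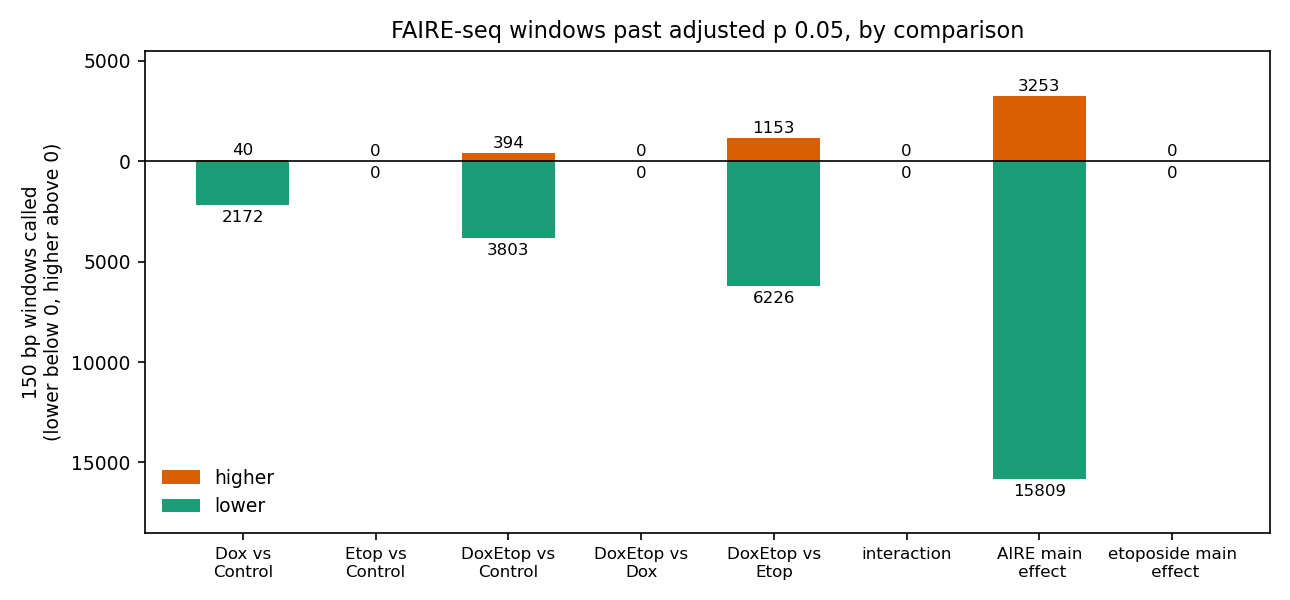
Number of 150 bp windows with an edgeR adjusted p under 0.05 in each comparison, with bars above 0 for windows higher in the first-named group and bars below 0 for windows lower. Each comparison of AIRE-induced with uninduced cells has more lower than higher windows, and the etoposide comparisons and the interaction have 0.

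The interaction, which asks whether both treatments together differ from the sum of each on the log2 scale, gave 0 windows by edgeR, by DESeq2 and by limma-voom, with 10610 (4.14%) at an unadjusted p under 0.05 by edgeR. The smallest p was at the window starting at 25574301 on chromosome 1, in the region named above for DoxEtop vs Etop, with an interaction of 3.79 (SE 0.765) on the log2 scale and an edgeR adjusted p of 1. Without Control replicate 2, 5 windows were called. The different counts of called windows in Dox vs Control and DoxEtop vs Etop are therefore not shown to be a difference in the effect of AIRE induction at any single window.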

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

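Each of 106 sets of 4 libraries, the induced or the other arm for a total, a score, a class median or a named window, was searched for a library far from the other 3, and 7 were found, where chance gives about 1 in 20 sets. The number found is near that rate. In regions of up to 300 bp, DoxEtop replicate 1 had a median level of -0.1668 against -0.0554 to -0.0339 in the other induced libraries. Among libraries without induction, Control replicate 1 had the highest median level on chromosome 2, 0.05503 against -0.0231 to -0.0171, and on chromosome 7, 0.05816 against -0.0202 to -0.014. Etop replicate 1 was lowest on chromosome 10, at -0.0007115 against 0.0484 to 0.0521, and Control replicate 2 on chromosome 16, at -0.08807 against 0.00679 to 0.0204. At the window starting at 232575051 on chromosome 2, DoxEtop replicate 1 had 10.07 CPM against 6.10 to 6.18 CPM in the other induced libraries. At the window starting at 226735551 on chromosome 1, DoxEtop replicate 2 had 0.989 CPM where the other induced libraries had 0. With those all at 0, any count would have been flagged, so the rate of 1 in 20 does not apply there.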

How the results depend on the processing

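Testing 1 window per region, thinning and other merging gaps were chosen after the data were seen. The counts of called windows for the AIRE comparisons changed most when single libraries were left out and with the test. Leaving out each library in turn gave 0 to 4091 windows for Dox vs Control (2212 with all), 0 to 6786 for DoxEtop vs Control (4197), 80 to 15686 for DoxEtop vs Etop (7379) and 7357 to 23722 for the AIRE main effect (19062). It gave 0 to 218 for Etop vs Control, 0 to 23 for the etoposide main effect and 0 to 5 for the interaction. A library left alone in its group is assumed to vary like the other groups, and a count can then fall through lost replication alone. In the order Dox vs Control, DoxEtop vs Control and DoxEtop vs Etop, loess offsets gave 918, 2489 and 4917 windows, DESeq2 258, 850 and 2255, limma-voom 5, 41 and 27, and 1 window per region, with fewer windows tested, 332, 539 and 1181. For the AIRE main effect limma-voom gave 859, 849 of them also called by edgeR, and 1 window per region gave 3019. The 4 libraries of a comparison alone gave 4262 for Dox vs Control and 13 for DoxEtop vs Dox, where limma-voom gave 8. For the etoposide main effect DESeq2 gave 3 and 1 window per region gave 1. In selections of windows added after the data were seen, the difference in regions of up to 300 bp (-0.235 in the whole table) was -0.233 with 274 windows left out, -0.157 with at least 129 counts before and after exchanging the arms, 0.00533 with 85936 windows kept by the level of both arms and -0.0385 with as many kept by summed count. With the windows classed by region width in the whole table it was -0.23, -0.188, -0.269 and -0.554. Lower windows made up 82.7%, 79.4%, 73.7% and 79.1% of the called windows in these selections. The replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated at -0.073 to 0.12. With the replicate number as a block, 5 windows were called for Etop vs Control, 7 for the etoposide main effect and 17999 for the AIRE main effect. With loess offsets, the windows at 36547201 on chromosome 19 and 226735551 on chromosome 1 turned from -5.26 and -4.79 to 0.258 and 0.353 in the AIRE main effect. Of the 20 named windows of the AIRE main effect, 18 were no longer called with limma-voom and all 10 lowest with loess offsets, and with limma-voom 0 of the 20 named windows in each of the 3 comparisons of group pairs were called. In the same order of comparisons, 20, 5 and 3 of the named windows were no longer called with DESeq2 and 17, 6 and 7 with loess offsets. Apart from the smaller number of windows or libraries where that applies, the cause of these differences was not tested. Scaling by DESeq2's size factors or column totals, the stricter filter and thinning kept all 8 counts within 1.5 times, and leaving out the filter changed nothing because it removed 0 windows. The gene lists and promoter classes were not run for want of hg19 annotation. At these depths, 1 of 100 simulated 2-fold changes was called in Dox vs Control, where few windows were changed and the adjustment was therefore stricter than in the real comparison.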

Other observations

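The tests in this part, with the segments and the counts over other splits of the libraries, were chosen after the results were seen. A window called lower with AIRE induction lay in 5805 regions, and in 23.9% of these every window was called lower. Of the 3539 regions of 1000 bp or more, 1090 held a window called lower, and in these a median of 11.8% of the region's windows were called lower. All 4 induced libraries were at or below 1 CPM at 319 windows, and all 4 libraries without induction at 0 windows, a comparison that the authors' minimum and the larger totals without induction can tilt. In selections of windows that treat both arms alike, the numbers were 254 and 0 at 111 counts with the arms exchanged, 69 and 0 at 129 counts, and 4 and 0 at a mean of both arms of at least 3.96 CPM. In counts, 382 windows in 228 regions had at most 5 in each induced library, with a median of 34 over the libraries without induction.

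Lower windows, 15809 of all 256141, were dense on the long arm of chromosome 19, though not only there. The segment from 36000001 to 37000000 held 3427 windows in 385 regions, of which 461 were lower and 36 higher with AIRE induction, and the segment from 44000001 to 45000000 had a median log2 fold change of -0.49 with 20.2% of windows lower. In the segment from 37000001 to 38000000, 26.1% of windows were lower. The segment from 1000001 to 2000000 on the same chromosome had a median above 0, at 0.213. Of its windows, 26 (2.01%) were called lower and 17 higher. The most negative median of the segments with at least 200 windows was -0.675, on chromosome 10 from 47000001 to 48000000, where 18.9% of windows were lower. On chromosome 1, 24.2% were lower from 234000001 to 235000000 and 21.6% from 223000001 to 224000000. The most positive medians were 0.48 on chromosome 2 from 242000001 to 243000000 and 0.406 on chromosome 8 from 145000001 to 146000000, both with 0 windows lower.

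The number of windows called for AIRE induction was set against other splits of the 8 libraries into 4 and 4, with 1 window per region. Of 34 splits that could be fitted, 1, the real one, gave as many as its 3019 windows, and the highest of the others gave 630. A share of 1 in 34 is the smallest these splits can give. They were also run after the first principal component had parted the same libraries, so chance is unlikely but not excluded. The split with 630 windows, which sets Control replicate 1 with both Dox libraries and DoxEtop replicate 1, differs from the real one only in exchanging Control replicate 1 and DoxEtop replicate 2. For etoposide the real split gave 1 window, 4 of 34 splits gave as many and the highest other gave 6, so chance is not excluded.

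Technical explanations for the excess of lower over higher windows with AIRE induction, 82.9% of all called windows, were each tested as its whole cause. Were it a product of windows near the authors' count minimum, it would be gone among the most covered windows, but 72% of 1932 called windows among the 10% of windows with the highest mean level were lower, as were 73.7% of 6281 among the 85936 windows chosen by the level of both arms alike. Were it a product of the higher totals of some libraries without induction at the testing step, thinning all libraries to equal totals would remove it, but 85.8% of 17286 called windows were then lower. Thinning cannot undo a tilt that higher totals gave through the authors' minimum, because the windows had been chosen before it. Were it a trend of fold change with mean level, loess offsets would remove it, but 73.8% of 15111 called windows were lower, although the 10 lowest named windows were no longer among them. The shares of 72%, 73.7% and 73.8% are below 82.9%. Mean level or the authors' choice of windows may therefore add to the excess, and these tests cannot exclude such a part. A difference between libraries in sequence composition or in the strength of FAIRE enrichment stays open, since neither the genome sequence nor input libraries were used here, and so does an effect of doxycycline itself, for which doxycycline without the transgene is the missing test.

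Control replicate 1 lay between Control replicate 2 and the Dox libraries. At 2023 regions with at least 1 window lower in DoxEtop than in Etop, in a fit to the 4 libraries of these groups alone, its mean was 3.38 CPM, against 6.10 in Control replicate 2 and 1.94 and 1.71 in the Dox libraries. A mislabelled induced library stays open. The level lies below 4.28 CPM, the upper end of a two-sided 95% prediction interval from only 2 Dox libraries. A limit for the upper side alone would be lower and was not computed, so this comparison alone decides nothing. The library also correlated with Dox replicate 1 (0.507) above its own replicate (0.488). Against mislabelling, it was above both Dox libraries in 79.5% of these regions. It also had 17 counts against 1 and 1 at 1620451 on chromosome 17. A fixed share of AIRE-induced material, or some induction without doxycycline, could give the same position between Dox and Control replicate 2 at regions that fell and at regions that rose. The positions differed by -0.016 (95% bootstrap interval over regions -0.221 to 0.196), too wide with 64 regions that rose in that fit and without the spread between cultures, so these explanations and a difference between cultures cannot be told apart.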
